A study of Nitratidesulfovibrio vulgaris str. Hildenborough with 11 samples.

How the data were processed

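The samples were cells of Desulfovibrio vulgaris Hildenborough, an anaerobic sulfate-reducing bacterium that is also filed under the genus name Nitratidesulfovibrio. Per the labels, the cells came from batch cultures in LS4D medium and were either left untreated or exposed to 250 mM NaCl, and RNA was taken at 0 and 120 min. The labels give 11 arrays in 4 groups: 3 untreated arrays at 0 min, 3 NaCl arrays at 0 min, 3 untreated arrays at 120 min and 2 NaCl arrays at 120 min. They do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be partly technical. On every array, per the labels, Cy5 marked the total RNA of the sample and Cy3 marked genomic DNA of the same strain, which served as a common reference.

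The deposited values were one log ratio per spot and array, for 9216 spots, and they are treated here as log2 ratios of the RNA channel over the genomic DNA channel. The base of the logarithm is not given in the sources used here. The widest span on an array was 14.7, which is a 26242-fold range in log2 and would be a 2.37 million-fold range in natural log. The direction is likely RNA over DNA, from the order of the channels in the labels, from a positive skew on all 11 arrays (0.68 to 1.01), and from the noise of duplicate spots. The median difference between duplicate spots was 0.26 in the lowest of 10 classes of probe positions by mean ratio and 0.14 to 0.17 in classes 6 to 10, as a dim RNA signal at low ratios would give. If the direction were opposite, all rises and falls would exchange places, and the lowest and highest level classes would too. The scanner, image software, background correction, spot filter and normalization are not given in the sources used here. The medians of the deposited columns ran from -2.00 to -0.84, so the arrays had not been brought to a common median.

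A total of 2011 spots had no value on any array, 7205 had a value on at least 1 array and 5466 had a value on all 11. The number of spots with a value was 6840 to 6999 per array. Signal brightness per channel is not used here, so the distance of a spot from background is unknown and the number of arrays limits the precision.

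Spots are known here by number only, and the table of genes used here holds no spot numbers, so no spot could be tied to a gene. For that reason the 24 gene lists fixed for this work (with their set tests), the named products and a planned check of the ratio's direction on ribosomal protein and sulfate reduction genes could not be run. The values themselves showed that each probe was printed in duplicate: the mean level of a spot correlated at 0.994 with that of the spot 4608 places later, against 0.49 at the next best distance of 6912. The 2 spots were averaged and are called a probe position, named by its first spot. Of 3610 positions with a value, 3595 had both spots measured. The 3491 positions with values on at least 2 arrays of every group were tested, and 119 were not.

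Each array was centred on its median over the tested positions. One linear model with a mean per group was fitted over all 11 arrays with limma 3.58.1 in R 4.3.3 (7 residual degrees of freedom, 4.78 prior degrees of freedom), and each comparison was tested as a contrast with moderated variances. The 5 comparisons were NaCl against untreated at 120 min, the same at 0 min, 120 against 0 min in untreated cells, 120 against 0 min in NaCl cells, and the difference of the NaCl effect between the times. P-values are two-sided and were adjusted by Benjamini-Hochberg within each comparison. A position is called higher or lower when its adjusted p was below 0.05. Plots were drawn with matplotlib 3.10.9.

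The groups, the tests, the alternatives and the rule for naming were set before the data were examined, apart from the choices said to be later. The plan was to average the spots of a gene, and the pairing of spots 4608 places apart was found from the values. The alternative of the first spot alone rests on that pairing. Without gene names, the rule allowed at most 2 positions that rose and 2 that fell in the comparison at 120 min, those with the largest changes among called positions whose arrays did not overlap between the groups. Positions were also divided into 5 and into 10 level classes of equal size by their mean centred ratio over all arrays, a grouping added after the data were seen. For the 10 pairs of replicate arrays, differences between arrays at the first spots correlated with those at the duplicate spots at 0.19 to 0.70. The lowest value was that of the 2 NaCl arrays at 120 min, whose spread may be largely technical. In each pair 0 to 1 values were identical. No array thus repeated the values of another, and each was counted as 1 sample, as the labels list it; this does not show whether the RNA came from separate cultures.

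The fit was tested on simulated data for the comparison at 120 min over 3491 positions. It recovered 37.3% of simulated log2 changes of 0.5, 95.5% of changes of 1 and 100% of changes of 2, and it called 6 of 3291 unchanged positions. The 3 sizes were given to 67, 67 and 66 positions, a far smaller share than the 50.7% called in the data. Values were drawn as normal and independent, with the same spread in all groups. The rates therefore check the fit and may differ for the real data. The alternatives were no centring, quantile normalization, positions with values on all arrays, keeping only the 2618 positions with the highest ratios, the first spot of each pair alone, a trended robust prior, array weights, only the groups compared, the replicate number as a block, a stricter threshold, a minimum change of 2-fold, and leaving out each array in turn.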

Results

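The series asked how gene expression in D. vulgaris differed between cells exposed to 250 mM NaCl and untreated cells at 0 and 120 min. Expression was read as the log2 ratio of RNA to genomic DNA at 3491 probe positions on 11 arrays. Array medians before centring lay between -2.00 and -0.84, and 6840 to 6999 spots per array carried a value. The median SD between arrays of a group was 0.18 in untreated cells at 0 min (n = 3), 0.13 in NaCl cells at 0 min (n = 3), 0.13 in untreated cells at 120 min (n = 3) and 0.13 in NaCl cells at 120 min (n = 2). At the same spread an SD from 2 arrays has a lower median than one from 3, so the last value reads too low. The difference between the 2 NaCl arrays at 120 min had an SD across positions of 0.32. For pairs of NaCl arrays at 0 min it was 0.25 to 0.29. For untreated pairs it was 0.26 to 0.31 at 120 min and 0.30 to 0.46 at 0 min. A higher ratio is likely more RNA, on the basis given with the processing.

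The 2 arrays of NaCl cells at 120 min stood apart from all others. They correlated with each other at 0.983 across positions, and with the untreated arrays at 120 min at 0.878 to 0.896. The untreated arrays at 120 min correlated among themselves at 0.983 to 0.988, and untreated and NaCl arrays at 0 min correlated with each other at a median of 0.974. Within the groups at 0 min, the untreated arrays correlated at 0.962 to 0.983 and the NaCl arrays at 0.985 to 0.989. In a principal component analysis of the 3414 positions with values on all arrays, the first component held 61.1% of the variance. It placed the NaCl arrays at 120 min at 36.2 and 39.4 and the other arrays between -14.4 and -3.15. The second component held 16.1% and placed untreated arrays at 0 min at 5.64 to 16.2, NaCl arrays at 0 min at 0.60 to 2.27, and untreated arrays at 120 min at -14.3 to -13.0.

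The main comparison was between NaCl and untreated cells at 120 min. The ratio was higher in NaCl at 1021 positions and lower at 749, together 50.7% of the 3491 tested. The median change was 0.85 on the log2 scale among the positions called higher and -0.70 among those called lower, sizes that the selection by the test raises. Over all tested positions, called or not, the SD of the change was 0.76 and the median SE of a position was 0.16. Changes of at least 2-fold were more often rises: 403 positions rose and 164 fell by that much, and of 74 called positions that changed at least 4-fold, 69 rose. Over all tested positions, called or not, the arrays of the groups did not overlap at 70.4%, where chance gives 20% with all 5 arrays measured. The split into rises and falls depended on the scaling: after quantile normalization 826 positions were higher and 945 lower, and without centring, where the median of all changes was -0.65, 146 were higher and 1234 lower. All changes are therefore relative to the median position of each array.

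The largest rise was at spot1517, where the centred log2 ratio was -0.27 ± 0.25 (SD, n = 3) in untreated cells and 4.38 ± 0.08 (SD, n = 2) in NaCl cells at 120 min. This is a log2 change of 4.66 with an SE of 0.20 (25.2-fold, limma adjusted p = 2.04e-08). At spot140 the ratio was 0.23 ± 0.08 (SD, n = 3) in untreated cells and 4.25 ± 0.33 (SD, n = 2) in NaCl cells, a log2 change of 4.01 with an SE of 0.18 (16.1-fold, limma adjusted p = 2.09e-08). The largest fall was at spot4489, from 2.25 ± 0.14 (SD, n = 3) in untreated cells to -0.36 ± 0.18 (SD, n = 2) in NaCl cells. The ratio there fell by 2.61 on the log2 scale with an SE of 0.13, which is 6.10-fold lower (limma adjusted p = 8.51e-08). At spot3943 it fell by 2.35 with an SE of 0.52, 5.11-fold lower (limma adjusted p = 0.0025). The untreated arrays at spot3943 were spread widely, with a mean of 5.11 ± 1.04 (SD, n = 3), while the NaCl arrays gave 2.75 ± 0.004 (SD, n = 2). The changes at all 4 positions were in the same direction and past the threshold in each of the 20 alternative fits made for them.

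**Figure D1:**
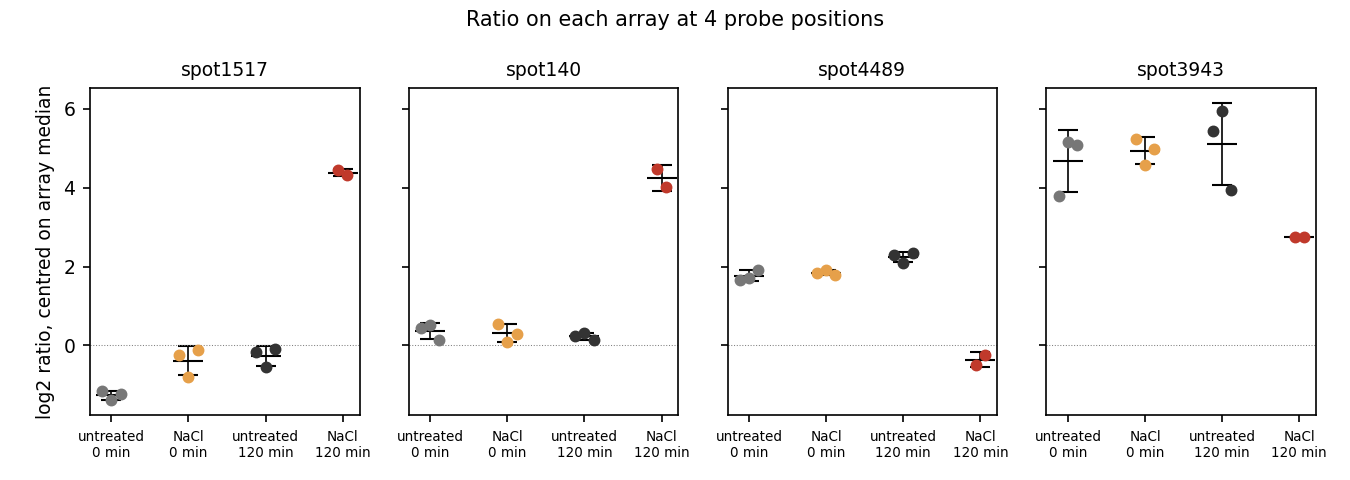
Centred log2 ratio (y axis) at 4 probe positions in the 4 groups (x axis). Each point is an array, and the horizontal bar and whiskers give the group mean and SD (n = 3, or n = 2 for NaCl at 120 min). At spot1517 the NaCl arrays at 120 min averaged 4.38 and those of untreated cells -0.27, and at spot4489 the averages were -0.36 and 2.25.

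Rises and falls were spread unevenly over the levels of the ratio, which are levels of expression only if the ratio is RNA over DNA. Of 5 level classes by mean ratio, the lowest held 699 positions, of which 229 were higher in NaCl and 83 lower at 120 min. In the middle class of 698 positions the numbers were 164 and 174. In the highest class of 698 positions 270 were higher and 150 lower, and this class also had the largest share of called positions, 60.2%, against 44.6% in the lowest class. The classes were set on all arrays, those at 120 min included, so a rise in NaCl itself moves a position towards the highest class. After quantile normalization the lowest class still had more rises than falls, 196 against 113, while the highest class turned to 157 rises against 259 falls. Without centring, falls outnumbered rises in both classes, with 29 rises and 155 falls in the lowest class and 57 rises and 259 falls in the highest. Centring does not make the arrays alike in spread or skew. The SD across positions was 1.74 and 1.71 on the NaCl arrays at 120 min and 1.55 to 1.69 on the others. Skewness was 0.93 and 1.01 on these NaCl arrays and 0.68 to 0.79 on the others.

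**Figure D2:**
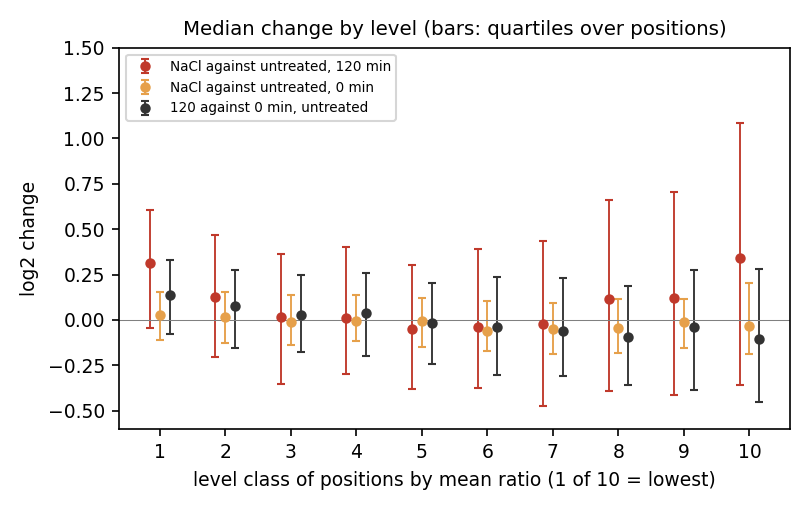
Median log2 change (y axis) in 10 level classes of the tested positions by mean centred ratio (x axis, class 1 is the lowest), for NaCl against untreated at 120 min, the same at 0 min, and 120 against 0 min in untreated cells. Bars span the quartiles over positions. At 120 min the median was 0.32 in the lowest class and 0.34 in the highest, which became 0.17 and -0.22 after quantile normalization and -0.41 and -0.39 without centring.

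At 0 min, NaCl and untreated cells differed at 35 of 3491 positions, 29 higher and 6 lower in NaCl. All 13 called differences of at least 2-fold were higher in NaCl, and the largest was 2.77 on the log2 scale. The ratio at spot1517 was higher in NaCl by 0.88 with an SE of 0.18 (limma adjusted p = 0.042), while the differences at spot140, spot4489 and spot3943 were -0.05, 0.08 and 0.26 and did not pass the test. Before adjustment 468 positions had p below 0.05. The number called depended on single arrays and settings: it was 4 without replicate 3 of NaCl at 0 min, 17 without replicate 1 and 22 without replicate 2 of that group, and 12 without replicate 2 of untreated cells at 0 min. It was 10 in a fit of the 6 arrays at 0 min alone and 5 without centring.

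The NaCl differences at 120 and 0 min, which share no arrays, correlated weakly across positions, with r = 0.097 (rho = 0.092; positions are not independent replicates). This r was 0.039 without replicate 2 of untreated cells at 0 min and 0.14 without replicate 1. Of the 29 positions higher in NaCl at 0 min, 17 were also higher at 120 min, where 8.48 would be shared by independent lists. Another 4 were lower at 120 min, where 6.22 would be shared. Of the 6 positions lower at 0 min, 2 were lower at 120 min and 2 higher, where 1.29 and 1.75 would be shared.

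In untreated cells, 942 positions changed between 0 and 120 min, 432 rising and 510 falling. Of these, 101 positions changed by at least 2-fold, 55 of them higher and 46 lower at 120 min. Median sizes among called positions were 0.60 for rises and -0.57 for falls. At spot1517 the ratio rose by 0.99 with an SE of 0.18 (limma adjusted p = 0.0023) and at spot4489 by 0.48 with an SE of 0.12 (limma adjusted p = 0.013), while spot140 and spot3943 gave -0.13 and 0.43 and did not pass. Rises were more frequent than falls in the lowest of the 5 level classes, 89 against 28, and less frequent in the highest, 97 against 148. Without centring 69 positions were called, 41 rising and 28 falling, and without replicate 2 of untreated cells at 120 min 613 were called.

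In NaCl cells, 1913 positions changed between 0 and 120 min, 1074 rising and 839 falling. Changes of at least 2-fold numbered 637, with 434 rises and 203 falls, and 85 called positions changed by at least 4-fold. The ratio at spot1517 rose by 4.77 with an SE of 0.20 (limma adjusted p = 1.43e-08), and that at spot140 rose by 3.93 with an SE of 0.18 (limma adjusted p = 2.49e-08). It fell by 2.20 at spot4489 with an SE of 0.13 (limma adjusted p = 2.55e-07) and at spot3943 it fell by 2.18 with an SE of 0.52 (limma adjusted p = 0.0037). Quantile normalization gave 845 rises and 1038 falls, and without centring 839 positions were called, 226 rising and 613 falling.

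Part of the change over time went the same way with and without NaCl. In both courses 230 positions rose and 239 fell, where independent lists would share 132.9 and 122.6. Another 157 positions were called in opposite directions. The changes over time in NaCl and in untreated cells, which share no arrays, correlated across positions with r = 0.32 (rho = 0.31). A further 1287 positions were called in NaCl cells and not in untreated cells, and at 789 of these the test of the difference between the courses passed as well. Of 316 positions called in untreated cells and not in NaCl cells, 111 passed that test.

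**Figure D3:**
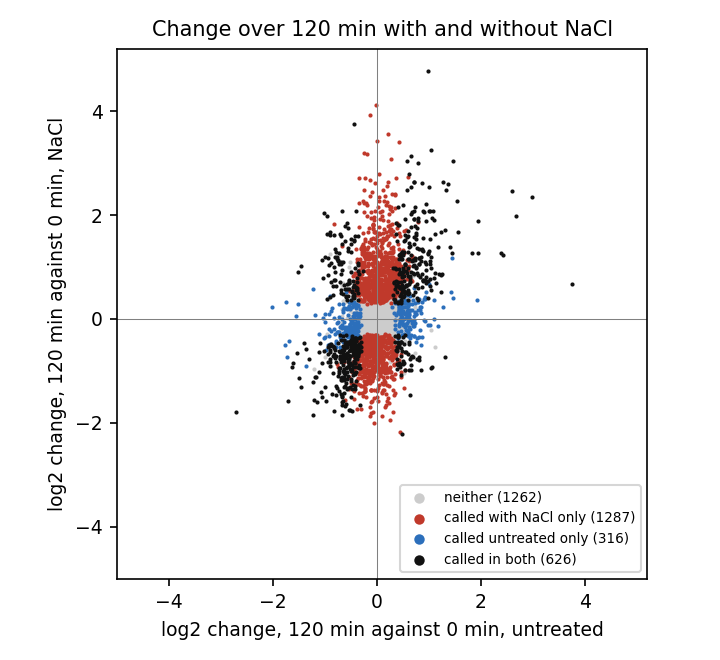
Log2 change from 0 to 120 min in untreated cells (x axis) and in NaCl cells (y axis) at 3491 probe positions. Each point is a position, coloured by the course in which it was called (adjusted p below 0.05), with 1287 called with NaCl only, 316 in untreated cells only and 626 in both, and the SD of the changes was 0.80 with NaCl and 0.44 without.

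The difference of the NaCl effect between 120 and 0 min, which is also the difference of the time courses, was called at 1241 positions, 742 higher and 499 lower. It reached at least 2-fold at 570 positions, 396 of them higher. Of the 1770 positions called at 120 min, 1175 (66.4%) were also called in this test with the same sign, and the 2 tests share the arrays at 120 min. The difference was 3.78 at spot1517 with an SE of 0.27 (limma adjusted p = 2.61e-06) and 4.07 at spot140 with an SE of 0.24 (limma adjusted p = 6.09e-07). It was -2.69 at spot4489 with an SE of 0.18 (limma adjusted p = 2.36e-06) and -2.61 at spot3943 with an SE of 0.69 (limma adjusted p = 0.012). Quantile normalization gave 603 higher and 671 lower positions, and without centring 286 were called, 96 higher and 190 lower.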

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

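The test of the difference between the NaCl effects at 120 and 0 min was planned. It singled out 1241 of 3491 positions at which the NaCl effect at 120 min was not the one at 0 min, 742 in the direction of a higher ratio and 499 in the direction of a lower one. The 4 named positions also passed it, but they had been chosen for their large changes at 120 min and this test uses the same arrays, so their calls are no separate evidence. The difference of effects was 3.78 at spot1517 (limma adjusted p = 2.61e-06) and 4.07 at spot140 (adjusted p = 6.09e-07). It was -2.69 at spot4489 (adjusted p = 2.36e-06) and -2.61 at spot3943 (adjusted p = 0.012). At spot1517 the ratio at 0 min was higher in NaCl cells than in untreated cells by 0.88. This call was marginal (limma adjusted p = 0.042), would not pass 0.01, and belongs to a list that depended on single arrays. At the other 3 positions the 0 min difference did not pass the test. With only 2 arrays for NaCl at 120 min, any handling shared by those arrays and by no others cannot be separated from the NaCl effect at that time.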

How the results depend on the processing

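The 4 named positions kept their direction and call in all 20 alternatives each, with log2 changes of 3.93 to 4.81 (spot1517), 3.28 to 4.24 (spot140), -3.34 to -2.48 (spot4489) and -3.08 to -1.93 (spot3943, highest adjusted p 0.0204). The count of 1770 positions at 120 min ran from 1341 to 1905 when each array was left out. The other ranges were 4 to 38 at 0 min, 613 to 947 for time in untreated cells, 1522 to 2066 for time in NaCl cells and 952 to 1285 for the difference of effects. Fits that left 1 NaCl array at 120 min assumed that it varied like the other groups.

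Without centring the counts fell to 5 at 0 min, 69 and 839 for time in untreated and NaCl cells, and 286 for the difference of effects, while the comparison at 120 min gave 1380, of which 895 were among the 1770. Differences between array medians then add to the spread and move all changes at 120 min by -0.73. Fitting the 0 min arrays alone gave 10 positions, and the cause was not tested. An adjusted p below 0.01 left 12, 437 and 747 positions at 0 min, for untreated time and for the difference of effects. By construction a minimum of 2-fold left fewer, 567 at 120 min, 13 at 0 min, 101 and 637 for time in untreated and NaCl cells, and 570 for the difference. With the replicate block the 5 counts were 1718, 37, 946, 1920 and 1178. The replicate numbers gave no clear sign of pairing. Of 15 same-numbered pairs, 4 had deviations correlating above 0.1 (range -0.20 to 0.26). Of 11 arrays, 2 correlated best with their own number in every other group that held it. Pairing is not excluded by this, because deviations from the mean of so small a group depend on each other. The median of the duplicate spots equals their mean and was not run, and the alternatives for gene lists could not be run without gene names. Signal over background is unknown, so how far low ratios are limited by it was not read from intensities.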

Other observations

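Of the tests in this part, the one without replicate 1 of untreated cells at 0 min, the one of a probe printed again, the random draws of positions the level classes under other scalings and the distances other than 2304 and its neighbours were chosen only after the results were seen. All correlations are across positions, which are not independent replicates.

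A set of 22 positions had values on all 3 untreated arrays at 120 min and on neither NaCl array at 120 min, and 0 positions had the reverse. Their median centred log2 ratio in untreated cells at 120 min was 1.67, above that of 84.0% of positions (below it, if the ratio runs the other way), and 20 of them had values on all arrays at 0 min. The 22 lay close together in spot order, with a median gap of 29 places, against 144 in 10000 random draws, of which 0 had a gap as small. The reverse pattern needed absence on 3 arrays rather than 2, so the counts of 22 and 0 are not like for like. The NaCl arrays at 120 min also had the fewest positions with a value, 3533 and 3523, against 3548 to 3575 on the others. They did not have the fewest spots with a value. Those were 6845 and 6840 on replicates 2 and 3 of untreated cells at 120 min, against 6894 and 6868 on the NaCl arrays. Why the 22 lacked values, for example through the spot filter, was not tested. The 22 were left out of all tests here, which required values on 2 arrays of every group.

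The NaCl difference at 0 min moved with the change over time in untreated cells, with r = 0.658 (rho = 0.640), and 32 of the 35 positions called at 0 min were called in the same direction over time, where independent lists would share 4.47. Both comparisons use the untreated arrays at 0 min, which that number leaves out, so part of the excess may come from them. Simulated unchanged groups against such arrays gave a mean r of 0.498 and a covariance of 0.0138, against an observed covariance of 0.0753. The simulations gave all groups the same spread at a position. The untreated arrays at 0 min were more variable, with a median SD of 0.18 against 0.13 in the other groups with n = 3. The simulated values for sharing all 3 arrays may thus be too low, and they do not measure how much sharing adds. Sharing of single arrays as the whole cause is argued against by dividing those arrays between the comparisons, which left a covariance of at least 0.0409. Replicate 1, the array farthest from its group, is argued against as the whole cause by a covariance of at least 0.0423 without it and with the other arrays divided, although r without it (0.619, arrays shared) lay within the simulated values (mean 0.600, highest 0.639). A handling difference common to all 3 untreated arrays at 0 min stays open, as does the untested hypothesis that the NaCl cells at 0 min may already have been further along the course that untreated cells followed by 120 min.

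Positions with the lowest ratios were higher in NaCl at 120 min, by a median of 0.32 in the lowest of 10 level classes (350 positions), and so were those in the highest, by 0.34. Quantile normalization left 0.17 in the lowest class and turned the highest to -0.22, and without centring the lowest class was at -0.41, above the median of all positions at -0.65. A dimmer RNA channel against a background floor would raise the lowest class. Within groups the level of this class followed the array median with a slope of 0.05 (SE 0.05), which predicted a change of -0.0341 (SE 0.037). This cannot decide on a floor, because array medians of a ratio need not follow RNA brightness and intensities were not read. Choosing the lowest class from the 0 min arrays alone gave 0.377, so selection on the tested arrays is argued against for that class. The highest class was not chosen again in this way. A rise of the lowest class was also seen without NaCl. Between 0 and 120 min in untreated cells the median change was 0.14 in the lowest class and -0.10 in the highest. A background floor and the authors' background correction and spot filter stay open for the lowest class, as does an effect of NaCl itself.

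Changes at 120 min were shared between positions 2304 places apart, the highest of 4408 distances searched, with r = 0.542 over 1704 pairs, and 442 pairs were called in the same direction and 76 in opposite directions, where 224.3 would be in the same direction if independent. A repeat of the same probe at all these pairs is argued against by the levels, which correlated at 0.487, while duplicate spots correlated at 0.994. Whether some of the pairs repeat a probe was not tested. At positions 1 place to either side of that distance r was at most 0.0231. Neighbours in spot order had deviations within groups that correlated (median r 0.096) while their changes did not (r = 0.006). These values would bear on an uneven array surface only if consecutive spots lay side by side, and the print layout is unknown here. Other distances also stood out, with r = 0.26 at 2324 and 0.22 at 20. Deviations within groups correlated at a median of 0.17 at 2304 and 0.12 at 20. An uneven surface or another effect of the print layout thus stays open. Whether such pairs hold probes of neighbouring or co-transcribed genes was not tested, since spots could not be tied to genes.

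Regrouping the arrays gives 10 splits for each comparison of 3 against 3, too few for a share under 0.05. At 0 min the labelled split called 35 positions and the highest of the others called 0, so 1 of the 10 splits reached that count. For the change over time in untreated cells the labelled split called 942 and the highest of the others 1. Every other split mixes arrays of both compared groups, so any difference between these groups adds to its spread and lowers its count. The low counts of the other splits are therefore no separate evidence.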
